A study of Drosophila melanogaster with 6 samples.

How the data were processed

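The samples were cell populations enriched for intestinal stem cells, sorted by GFP from dissociated fly midguts, in 3 batches of young flies (6 to 8 days) and 3 batches of old flies (59 to 65 days). Per the labels' protocols, libraries were made with the Illumina TruSeq RNA kit in its second version, which does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name FastQC, Bowtie, TopHat 1.2.0, edgeR and the genome build dm3, with no role or order. How the authors counted reads that map to several places is not given in the sources used here.

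The authors deposited 2 tables, 1 of all gene rows and 1 of the rows with an adjusted p under 0.05. Per the file headers, the authors' values are a log2 fold change, a mean abundance on the log2 scale of CPM, a p-value and an adjusted p-value (FDR). The name of the first table speaks of an exact test. The second table's 580 rows were the rows of the first with an adjusted p under 0.05. The deposited adjusted p-value equals a Benjamini-Hochberg adjustment of the deposited p-value over all 8164 rows, with a largest difference of 2.56e-15. Each table also held 12 columns of values per library, 6 of counts and 6 of CPM. Their names hold a letter, a or b, and a number from 1 to 3, which form 2 sets of 3 but match no sample label. They were therefore given to no sample or group and entered no computation, neither by age nor as unnamed sets. When their unit was determined, nearly all reads of CG9468 and of the row granny-smith;CG14384 were seen in a single library column, and this is stated beside the value of CG9468. Other rows were not examined for it systematically. For the same reason the depth per library is not given here, nor any interval that needs it.

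The planned comparison was a quasi-likelihood fit on counts per library, with tests of gene lists, levels per library and overlap with the deposited list. None of these was run, because columns that match no sample label were not used. The plan foresaw a description of the authors' deposited comparison, with no gene test added, for files without values per library, and the same was done here. Rows are named as called where the deposited adjusted p is under 0.05. The sign of the log2 fold change is reported as given, because the numerator is not stated in the sources used here. The 3 batches per age are separate batches of midguts per the labels, and p-values of the deposited comparison measure the spread between them as the authors modelled it.

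Gene rows were joined to gene identifiers through their transcript identifiers, using the BDGP6 annotation of Ensembl release 115 for names only. At least 1 transcript matched for 7726 rows, or 94.6%. Coordinates are those of the table in dm3, written 1-based. In 7571 rows a single gene is named, in 589 several, and in 4 the name is unreadable. Lists were tested on single-gene rows, and rows of several genes are named only where said. The row LKR was left out of the lists because its transcript belongs to another gene than the leucokinin receptor.

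The 26 gene lists were fixed before the data were examined. For the 23 lists with at least 3 measured members, positive and negative calls were each compared with the other single-gene rows by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 46 tests. This replaced the planned list test, which needs values per library, and was chosen after the data were seen. It treats genes as independent, which they are not, so its p-values are likely too small for genes that vary together. Odds ratios have 0.5 added to each cell. Each list's median log2 fold change was placed among 10000 random lists of its size, drawn from 20 bins of mean abundance. Both methods were tested on simulated data over the 7571 single-gene rows. Of 100 lists with 8 of 20 members planted as called, 100 had a Fisher p under 0.05, against 2 of 100 unchanged lists. Planting 8 of 20 members made a small Fisher p certain beforehand, so the count of planted lists says nothing about weaker enrichment. Of 100 lists with shifted fold changes, 96 lay above the central 95% of random medians, and 6 of 100 unchanged lists lay outside it. The simulation drew each gene independently of the others and of abundance. It therefore does not test how either method behaves where genes vary together, and the random lists too treat genes as independent. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

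The rule for named genes was set before the data were examined. It took, among rows with an adjusted p under 0.05 and a mean of at least 5 CPM, the 10 genes with the largest log2 fold change in each direction that have a name and the 3 largest that the table names only by a number. It also took up to 4 called members per list with the smallest p, and 14 genes whatever their p, in both cases with no minimum abundance. For counts the rule had a floor of 20 on average per library, and for normalized values a floor of 5. The latter was used, because counts were not. Its condition that libraries of the ages do not overlap was not applied. Rows of several genes and the 15 rows of near-equal values were not named under its first part, an exclusion chosen after the data were seen. The alternatives tried were a stricter threshold, a Benjamini-Yekutieli adjustment, minimum abundances of 1 and 5 CPM, single-gene rows, identical rows counted once, removal of the 15 rows, a 2-fold minimum, list members in no other list, and lists that include rows of several genes.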

Results

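RNA was sequenced from midgut cells of the fruit fly that had been sorted for GFP driven by escargot-GAL4, a driver active in intestinal stem cells and their immediate daughters. The series held 6 libraries, 3 from young flies of 6 to 8 days and 3 from old flies of 59 to 65 days, each from its own batch of midguts. The question was which transcripts of this stem cell enriched population differ between young and old animals. Values per library entered no computation and the depth of each library is not given here, because no label ties the library columns to an age. The account therefore rests on the comparison of the ages in the authors' deposited table, which gives a log2 fold change, a mean abundance as log2 CPM, reads scaled to a fixed library total, a p-value and an adjusted p-value per gene row. The sources used here do not say which age is the numerator of that fold change, so each difference has a sign and no age direction. A shared sign means that genes differed between the ages in the same direction.

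Among the lists tested, those of peptide hormones and of secretory granule and synaptic genes held more positive calls than the other genes of the table. In the authors' deposited table, the gut hormone gene Ast-C (FBgn0032336, dm3 2L from 11076165 to 11081397) had a log2 fold change of 2.78 at a mean of 120.2 CPM, with an adjusted p of 1.09e-12. CG13565, which encodes the neuropeptide Orcokinin (FBgn0034935, 2R from 19834482 to 19836137), had 2.60 in the authors' deposited table at a mean of 696 CPM, with an adjusted p of 3.45e-11. The synaptotagmin gene Sytalpha (FBgn0261089, 2L from 17592864 to 17603288) stood at 3.18 in the authors' deposited table, with an adjusted p of 3.49e-16. Markers of the progenitor cells themselves held 1 call among 11 measured. Their median of -0.41 lay at percentile 22.06 of random lists matched on abundance, and 9 had a negative sign. The gene whose driver marked the sorted cells, esg, had a log2 fold change of -0.41 in the authors' deposited table. Its mean was 835 CPM and its adjusted p 0.548 in the authors' deposited table.

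The authors' deposited table held 8164 gene rows, of which 580 had an adjusted p under 0.05. Of these called rows in the authors' deposited table, 422 were positive and 158 negative, so 72.8% shared the positive sign. The median log2 fold change was 1.51 among the positive and -1.33 among the negative called rows of the authors' deposited table. Called rows were less abundant than the table as a whole, with a median of 3.99 CPM against 15.3 CPM in the authors' deposited table. Of the 580 called rows, 318 lay under 5 CPM, and called list members are named below whatever their abundance. At a minimum of 5 CPM for all rows, an alternative chosen after the data were seen, 228 rows were called. The comparison columns of the authors' deposited table give no standard error and the library columns were not used, so no error stands beside a fold change, and whether a single library sets a value was not tested.

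**Figure D1:**
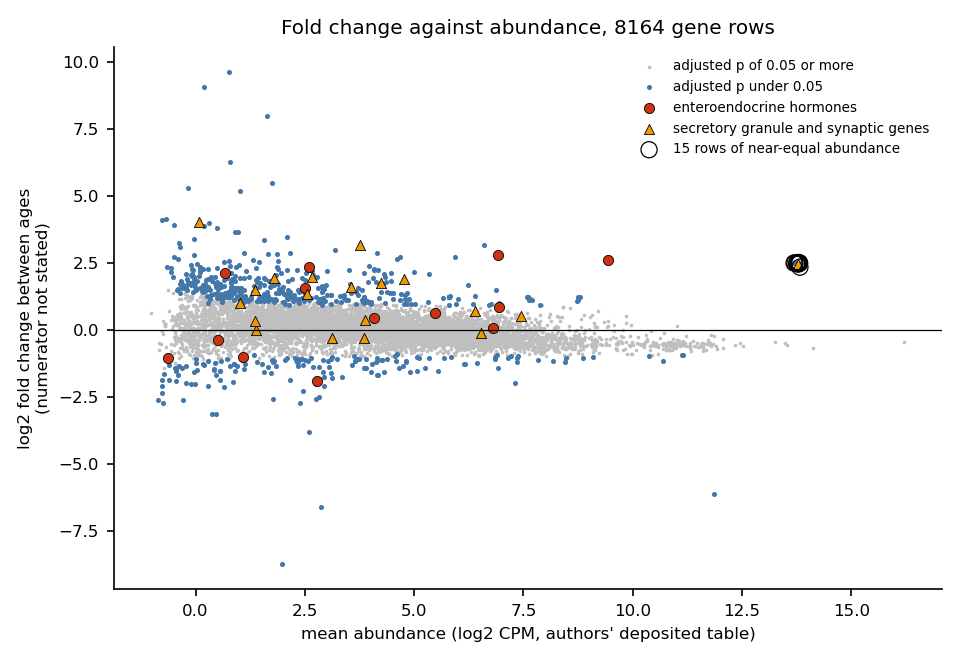
Each point is a gene row of the authors' deposited table, with mean abundance in log2 CPM on the horizontal axis and the log2 fold change between the ages on the vertical axis, whose numerator is not stated. Blue points are the 580 rows with an adjusted p under 0.05, red circles and orange triangles are the hormone and secretory lists, and open circles mark 15 rows of near-equal abundance between 13.69 and 13.82 log2 CPM.

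Peptide hormones of enteroendocrine cells, the secretory cells of the midgut, were tested as a list of 13 measured genes. Of these, 6 were called positive, 1 was called negative and 6 did not pass the test. Positive calls were more frequent than in the other single-gene rows, with an odds ratio of 15.9 and an adjusted p of 0.000577 by a two-sided Fisher's exact test. Adjusted over the list alone, 7 members were positive and 3 negative. Besides Ast-C and CG13565, the authors' deposited table gave CG14358, which encodes CCHamide-1 (FBgn0038199, 3R from 9918215 to 9922557), a log2 fold change of 2.34 with an adjusted p of 1.07e-07. Neuropeptide F, listed as npf, had 0.87 in the authors' deposited table at 122 CPM, with an adjusted p of 0.00664. Tachykinin (Tk), another hormone of these cells, had 0.63 with an adjusted p of 0.0805 in the authors' deposited table, and itp had 0.07 with an adjusted p of 0.889. The negative call was sNPF (FBgn0032840, 2L from 20027915 to 20056375), at -1.90 in the authors' deposited table with an adjusted p of 1.5e-05. It lies in a stretch of 2L where all 18 measured rows had a negative sign. Dh31 shared its row with the gene Bace, and that row had a log2 fold change of -0.29 in the authors' deposited table with an adjusted p of 0.953.

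The list of secretory granule and synaptic genes joins hormone processing and vesicle release with general neuronal genes. Of 19 measured members, 11 were called positive and none negative, with an odds ratio of 25.1 and an adjusted p of 1.71e-08 for positive calls by Fisher's exact test. Their median log2 fold change of 1.32 lay above those of all 10000 random lists matched on abundance, and 12 members were positive adjusted over the list alone. The prohormone convertase gene amon (FBgn0023179, 3R from 22523418 to 22539881) had 1.91 in the authors' deposited table at 27.3 CPM, with an adjusted p of 1.2e-06. Syt4 had a log2 fold change of 4.04 in the authors' deposited table, at a mean of only 1.06 CPM, with an adjusted p of 2.56e-11. The call of Snap25, 2.47 in the authors' deposited table, is uncertain because its row is one of 15 with nearly equal values. Without these 15 rows, 10 of 18 members were positive, with an adjusted p of 1.36e-07 by Fisher's exact test. The neuronal genes brp and nrv3 were among the positive calls in the authors' deposited table, and elav and cac were not called. Among 8 regulators of enteroendocrine fate, the proneural genes tap and ase were called positive. They had 2.58 and 1.66 in the authors' deposited table, at means of only 3.69 and 1.38 CPM. The marker of the mature cells, pros, had 0.70 in the authors' deposited table, with an adjusted p of 0.191. This list did not pass the test for positive calls, with an adjusted p of 0.358 by Fisher's exact test.

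**Figure D2:**
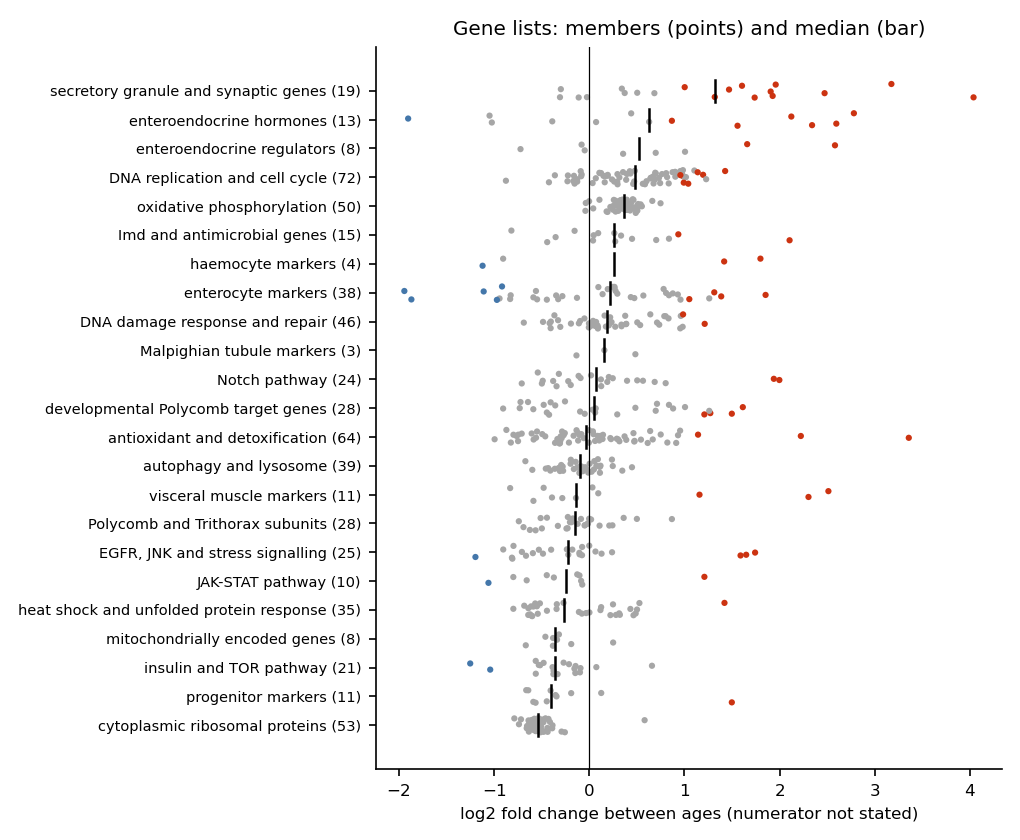
Each point is a list member in a single-gene row, placed at its log2 fold change between the ages in the authors' deposited table, whose numerator is not stated. Lists with at least 3 measured members are ordered by their median, drawn as a bar, with the number of members in brackets. Red points are called positive, blue points negative and grey points neither, and the secretory and hormone lists have the highest medians, 1.32 and 0.63.

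Among 11 measured progenitor markers, sna, which encodes a transcription factor related to Escargot (FBgn0003448, 2L from 15476593 to 15478269), was the only call, at 1.50 in the authors' deposited table with an adjusted p of 0.000315. The other named markers did not pass the test in the authors' deposited table, with 0.13 for the Notch ligand gene Dl (adjusted p 0.909) and -0.64 for Sox21a (adjusted p 0.280). The list's median was -0.41, with 9 of 11 signs negative, against -0.31 as the median over random lists matched on abundance. Enterocyte markers went both ways. Of 38 measured, 5 were called negative and 4 positive, and negative calls were more frequent than in other rows, with an odds ratio of 8.70 and an adjusted p of 0.0108 by Fisher's exact test, while the median of the list was 0.22. Adjusted over the list alone, 8 were positive and 7 negative. The enterocyte call ended at a minimum of a 2-fold difference, with an adjusted p of 0.273, and its adjusted p lay between 0.00503 and 0.339 over the alternatives tried. The protease gene Jon25Bi and the peptidase gene Ance were negative, at means of only 1.81 and 1.47 CPM. They had -1.94 and -1.87 in the authors' deposited table, with adjusted p of 6.19e-06 and 7.35e-05. The negative calls Jon99Cii and Jon99Ciii had nearly equal values in the authors' deposited table, -0.97 and -0.92 at 4.56 and 4.60 log2 CPM. They may therefore not be independent calls. The maltase gene LvpH and CG31004, the junction gene mesh, were positive at 1.85 and 1.31 in the authors' deposited table, with adjusted p of 9.77e-06 and 0.00667. The enterocyte genes Myo31DF and nub had -0.56 and 0.84 in the authors' deposited table, with adjusted p of 0.402 and 0.221.

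Few markers of other cell types had a row of their own in the authors' deposited table. Visceral muscle had 11 measured markers with 3 positive calls, an adjusted p of 0.158 by Fisher's exact test, and the call of sls among them belongs to the 15 rows of near-equal values. The troponin gene up was positive at 2.30 in the authors' deposited table with an adjusted p of 8.23e-07, and Zasp66 at 1.16 with an adjusted p of 0.0445, though the span of Zasp66 contains that of Cdc6. Mhc was not analysed here. Of 4 haemocyte markers, Sr-CI and lz were positive at 1.80 and 1.42 and crq was negative at -1.12 in the authors' deposited table, and neither direction passed Fisher's exact test, with adjusted p of 0.158 and 0.378. Fbp1 was negative at -0.94 in the authors' deposited table, with an adjusted p of 0.0381, and was 1 of 2 measured fat body and ovary markers. No call was made among 3 Malpighian tubule markers, 2 sex-biased markers and 1 tracheal marker in the authors' deposited table, where unadjusted p-values under 0.05 also numbered 0.

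Genes of DNA replication and the cell cycle leaned to the positive sign with few calls. Of 72 measured, 7 were positive and none negative, and 59 had a positive sign. The median of 0.48 lay above all random lists matched on abundance, whereas the share of positive calls did not pass Fisher's exact test, with an adjusted p of 0.439. Adjusted over the list alone, 16 were positive and 1 negative. The ribonucleotide reductase gene RnrS (FBgn0011704) had 1.04 in the authors' deposited table with an adjusted p of 0.0276, and the mitotic kinase gene polo 0.99 with an adjusted p of 0.0349. The clamp gene mus209, which encodes PCNA, had 0.99 in the authors' deposited table with an adjusted p of 0.0425. The call of Cdc6, 1.43 in the authors' deposited table, is uncertain because it overlaps Zasp66. The phosphatase gene stg, which drives entry into mitosis, had 0.92 with an adjusted p of 0.193 in the authors' deposited table. Of 46 genes of DNA damage response and repair, mus209 and the exonuclease gene tos were positive, the latter at 1.21 in the authors' deposited table, and the list had an adjusted p of 1 by Fisher's exact test.

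No subunit of the Polycomb and Trithorax complexes was called among 28 measured in the authors' deposited table, where 3 had an unadjusted p under 0.05. Pc had 0.24 and E(z) -0.20 in the authors' deposited table, with adjusted p of 0.702 and 0.754. Of 28 measured developmental genes known as Polycomb targets, sna, dac, tup and Abd-B were positive and none was negative. They had 1.50, 1.61, 1.21 and 1.27 in the authors' deposited table. The means of dac, tup and Abd-B were only 2.75, 2.83 and 1.76 CPM. Positive calls in that list did not pass Fisher's exact test, with an adjusted p of 0.358.

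Signalling and stress lists held 1 to 4 calls each, and none passed Fisher's exact test. In the JAK-STAT list of 10, chinmo was positive at 1.21 and the feedback inhibitor gene Socs36E negative at -1.06 in the authors' deposited table, while the ligand gene upd3 had -0.09 with an adjusted p of 0.917. Of 25 genes of EGFR, JNK and stress signalling, the cell death genes rpr and grim and the EGFR feedback gene kek1 were positive. They had 1.74, 1.59 and 1.65 in the authors' deposited table, at means of only 0.94, 1.76 and 1.56 CPM. The EGFR inhibitor gene sty was negative at -1.20 in the authors' deposited table with an adjusted p of 0.00861, and puc, a JNK target, had -0.81 with an adjusted p of 0.149. Of 24 Notch pathway genes, the target genes E(spl) and HLHmdelta were positive in the authors' deposited table, the former at 1.94, with adjusted p of 3.13e-05 and 0.00107. Their means were only 3.46 and 1.06 CPM. The more abundant targets HLHmbeta, HLHm3 and malpha were not called, at -0.32, -0.38 and -0.54 in the authors' deposited table. Of the 24 Notch pathway genes, 13 had a positive sign and 11 a negative sign. Of 15 immune genes, the antimicrobial peptide gene AttD and the peptidoglycan amidase gene PGRP-LB were positive at 2.11 and 0.94 in the authors' deposited table. Of 21 insulin and TOR genes, the receptor gene InR and CG11299, the sestrin gene, were negative at -1.25 and -1.04 in the authors' deposited table, with adjusted p of 0.00496 and 0.0294. Of 64 antioxidant and detoxification genes, Cyp6d2, GstE10 and Cyp4p1 were positive at 3.36, 2.22 and 1.14 in the authors' deposited table. Their means were 2.97, 0.96 and 22.8 CPM. Of 35 heat shock and unfolded protein response genes, CG10420 alone was called, at 1.42 in the authors' deposited table.

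Lists of housekeeping genes had no call in the authors' deposited table. Of 50 oxidative phosphorylation genes, 47 had a positive sign, with a median of 0.36 that lay above all random lists matched on abundance, and 1 had an unadjusted p under 0.05. Of 53 cytoplasmic ribosomal protein genes, 52 had a negative sign, with a median of -0.54 at percentile 3.25 of the random lists, and 21 had an unadjusted p under 0.05. All 140 rows of at least 1024 CPM in the authors' deposited table, ribosomal protein genes included and the 15 rows of near-equal values left out, had a median of -0.56. Of these 140 rows, 139 had a negative sign, whereas the median over all gene rows was 0.05. The negative sign of the ribosomal protein genes is therefore not particular to them among abundant rows. The 39 autophagy and lysosome genes had a median of -0.09 and 1 unadjusted p under 0.05. The 8 mitochondrially encoded genes had a median of -0.36 and 1 unadjusted p under 0.05.

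The largest positive log2 fold changes at 5 CPM or more that are not given above belonged to genes of several kinds. Ir85a, an ionotropic receptor gene, had 2.89 in the authors' deposited table, though its span overlaps another called row. Snmp had 2.21 in the authors' deposited table, Pal, which encodes an enzyme of peptide amidation, 2.07, the mucin gene Muc68E 2.03, Rab3, a member of the secretory list, 1.96, unc-13-4A 1.95 and the nuclear envelope gene kuk 1.92. Among genes that the table names only by a number, CG4577 had 3.17, CG11671 2.97 and CG14989 2.72 in the authors' deposited table. On the negative side, Kua (FBgn0032850, 2L from 20097858 to 20103375) had -3.83 in the authors' deposited table with an adjusted p of 6.17e-18, and lies in the stretch of 2L that also holds sNPF. Its span overlaps that of mRpS18B, which was called negative at -1.14 in the authors' deposited table. The mucin gene Muc68Ca had -2.09 in the authors' deposited table, the chitin synthase gene CS-2 -1.97 at 159 CPM, the muscle gene zormin -1.67, aay -1.55, Atet -1.44, miniature (m) -1.43, the flotillin gene Flo -1.42 and the noncoding RNA pncr009:3L -1.39. The spans of aay and m overlap other called rows. CG9468 had -6.63 in the authors' deposited table, but nearly all of its reads were seen in a single library column when the table was first read, so this value is uncertain. Other genes were not examined for this systematically. CG17145 had -2.75 and CG30043 -2.60 in the authors' deposited table.

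**Figure D3:**
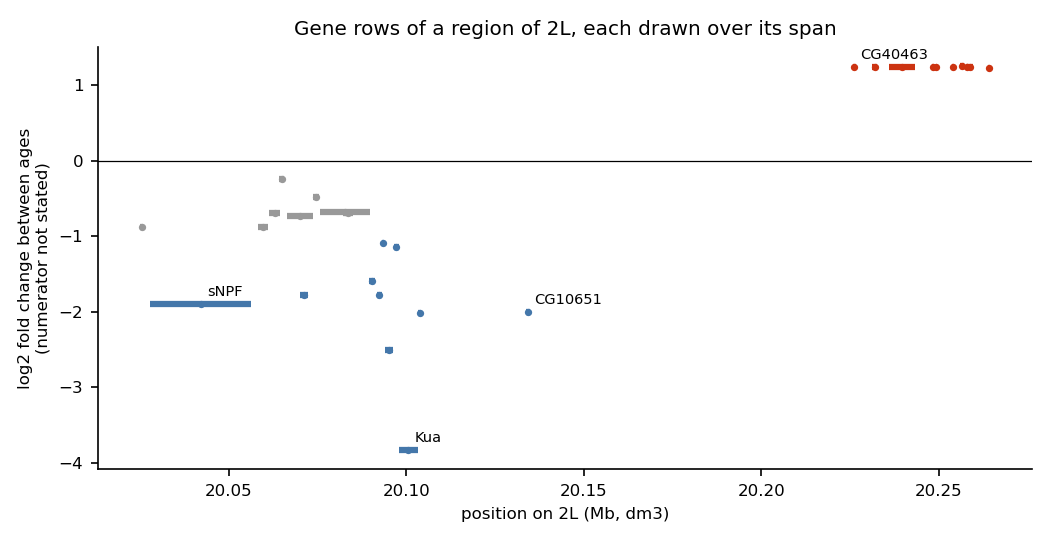
Each bar is a gene row of 2L, drawn over its span in Mb of dm3 at its log2 fold change between the ages in the authors' deposited table, whose numerator is not stated. Blue rows are called negative, red rows positive and grey rows neither. The 18 rows from 20025113 to 20134901 all lie below 0, with Kua lowest at -3.83, and 8 of the red rows carry 1 identical value, 1.24.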

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

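All alternatives here were chosen after the data were seen, except list members in no other list. A threshold of 0.01 left 376 called rows, of which 86 were negative. A Benjamini-Yekutieli adjustment left 337, of which 260 were positive and 77 negative, and a minimum of 5 CPM left 228, of which 149 were positive and 79 negative. By construction the first and second are stricter, and the third tests fewer rows. The enterocyte call for negative members was lost at the 0.01 threshold (adjusted p 0.0874), under Benjamini-Yekutieli (0.339) and at a 2-fold minimum (0.273), where fewer members are called. The other counts of called rows were within 1.5 times the reported ones, with 497 to 572 in all, and the share of positive calls ranged from 65.4% to 77.2%. Positive calls of the hormone list kept an adjusted Fisher p between 2.29e-05 and 0.00649 under the alternatives tried, and those of the secretory list between 4.84e-11 and 3.43e-07. Limiting the table to single-gene rows is no test of the lists, which used such rows already. Neither leaving out members shared with other lists nor counting identical rows once changed the members or calls of the hormone and secretory lists. These settings are therefore hardly a test of those lists. Of 69 named genes that were called, 52 stayed called under every alternative that kept their row.

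No paired analysis was possible because the library columns match no sample label and were not used, and the gene results come from the authors' deposited table. For the same reason alternatives set before the data were examined for normalization, filter on counts, test, list test, library sizes, pseudocount and leaving out each library were not run, and other splits of the samples were not counted. How far a single library sets a call was not tested. A mean of 1 CPM or less lies behind 67 of the 580 called rows.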

Other observations

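All tests in this part were chosen after the results were seen. The lists of receptors, ion channels and piRNA genes below were written after the called rows had been inspected, so their p-values are no independent evidence. Of 18 measured receptors for neuropeptides and amines, 9 were called positive and 1 negative, with an adjusted p of 5.24e-07 for positive calls by Fisher's exact test over these 3 lists in both directions. The neuropeptide F receptor gene NPFR1 had a log2 fold change of 1.80 in the authors' deposited table at 15.4 CPM, and the CCHamide-1 receptor gene CG30106 had 2.60 at 2.49 CPM. Octbeta3R was positive at 2.84, in a span that overlaps another called row, and Octbeta2R was negative at -3.15 in the authors' deposited table. Ion channel genes, with the channel regulator gene Slob counted among them, had 5 positive calls among 26, an adjusted p of 0.0206 by Fisher's exact test. The list's median was negative at -0.20, at percentile 0.8 of random lists matched on abundance. The positive calls include Slob, slo at 1.40 and the calcium channel genes stj and Ca-alpha1D at 2.35 and 1.81 in the authors' deposited table. Of 17 genes of the piRNA pathway, which silences transposons, 4 were positive and none negative, with an adjusted p of 0.0206 by Fisher's exact test. These were zuc, del, krimp and spn-E, at 1.68, 1.09, 1.14 and 1.15 in the authors' deposited table.

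Positive calls were frequent among hormone genes, 6 of 13, and among secretory granule and synaptic genes, 11 of 19, though sNPF was called negative, and 2 explanations from cell composition were tested. A uniform change in the share of enteroendocrine cells would move the abundant hormones alike only if no other sorted cells expressed them. Over the 5 hormone genes of at least 32 CPM the log2 fold change spanned 2.71. In the authors' deposited table it ran from 0.07 for itp to 2.78 for Ast-C. Single-gene rows as abundant had an SD of 0.42. This spread argues against a uniform change as the whole cause only under that condition, which was not tested. The spread had been seen before this comparison was chosen. A lower share of progenitor cells at 1 age that raised all other cell types alike would raise secretory and enterocyte markers alike. The medians of these lists differed by 0.94 with a permutation p of 0.0021, which argues against such an even rise. The secretory list was picked for this test after its high median was seen, so this p is no independent evidence. An uneven rise was not tested. Of 11 progenitor markers, 9 had a negative sign, with a median of -0.41 at percentile 22.06 of random lists matched on abundance. A change in the mix of enteroendocrine subtypes, or in hormone genes within progenitor cells, may underlie the pattern. The first would need mature enteroendocrine cells, which a sort on escargot-driven GFP is meant to leave out, to have passed it. Both stay open, as do an even or uneven effect of fewer progenitor cells and age itself. A uniform change where other sorted cells express these hormones stays open too.

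The 15 called rows with a mean of 13204 to 14484 CPM lie on 5 chromosome arms and had log2 fold changes from 2.34 to 2.51 in the authors' deposited table. Their SD of 0.0419 was below the smallest of 10000 draws of as many other positive rows, 0.102, as a single pool of reads counted in all of them would give. The draws came from positive called rows of any abundance. The closeness of the 15 rows had been seen beforehand, so the SD describes it and is no independent test. Their median span was 52529 bp, above the largest of 10000 draws of other called rows, 25771 bp, so a repeated sequence within long genes is a candidate source. They make up 21.0% of the summed mean CPM, and the genes they name, Gprk2, Nipped-A, bbg, Lasp, sls, Snap25, rut and for among them, are best read as 1 uncertain signal. Which sequence it is was not tested, and a real difference in that sequence between the ages stays open.

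Called rows lay beside called rows of the same sign more often than chance gives. There were 84 such neighbours in the authors' deposited table, against a mean of 24.8 in 10000 permutations. With identical rows counted once, the 15 rows left out and overlapping spans not counted, 55 remained, above the highest permuted value of 36. This argues against counts shared by overlapping or identical rows as the whole cause. Rows that may share reads without overlapping were kept, such as CG17571 and CG17570 on 2L. These had 1.25 and 1.23 in the authors' deposited table, beside 8 rows at 1.24, so such sharing is not excluded. On 2L, 18 consecutive rows from 20025113 to 20134901 all had a negative sign with a median of -1.12, and 10 of them were called. A single sign throughout is not particular to this stretch, since 6 of the other windows of 18 rows also had one, but the lowest median of such a window elsewhere was -0.59. Over all called neighbours of the same sign, a local difference in the DNA of the flies, shared regulation or paralogs side by side may each contribute. None of these was tested.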
